A study of Mus musculus with 2 samples.

How the data were processed

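Regenerating digit tips of adult mice were profiled by droplet single-cell RNA sequencing (10x Genomics, 3' libraries with unique molecular identifiers, UMIs). There were 2 libraries, 1 from a PdgfraCreERT line and 1 from an Lmx1bCreERT2 line, both carrying a tdTomato reporter at Rosa26 that is switched on by recombination. Per the labels, mice aged 10 to 12 weeks received 3 mg of tamoxifen per day for 4 days, digits were amputated 10 days later, and tissue distal to the amputation was taken at 14 days. Tissue was digested in Liberase at 280 µg/ml and passed through a 20 µm strainer, per the labels' protocols. No sort on tdTomato was described.

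The deposited values were raw UMI counts per gene and barcode, made by the authors with Cell Ranger 4.0.0, per the file headers, against mm10 with the tdTomato sequence added, per the labels' protocols. Which barcodes were kept as cells before deposit was not stated. The matrices held 28001 features, of which 27645 matched an ID of the GENCODE vM21 annotation of the same build. The Lmx1b library had 5991 barcodes and 66867027 UMIs, and the Pdgfra library 5032 barcodes and 49084751 UMIs.

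From these counts, barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept. In the Lmx1b library 1504 barcodes had under 500 genes and 2785 were over the mitochondrial limit, 3198 failing either. In the Pdgfra library the numbers were 1410, 2219 and 2658. Doublets were scored per library with Scrublet as implemented in scanpy, on all barcodes before these filters. The highest-scoring 0.8% per 1000 barcodes were taken out, 287 in the Lmx1b and 203 in the Pdgfra library. Most of these had failed the filters already, so the step removed only 49 and 65 barcodes among those that passed. Scrublet's own automatic threshold marked 0 barcodes in either library and so had not worked. There remained 2744 cells with a median of 17084 UMIs and 4163 genes in the Lmx1b library, and 2309 cells with a median of 9774 UMIs and 3142 genes in the Pdgfra library.

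Both libraries were clustered together without batch integration, on log(1 + counts per 10000) of 2000 variable genes chosen within libraries (tdTomato, Xist and Y-linked genes left out), 30 principal components, 15 neighbours and Leiden resolution 1.0. The 28 clusters were named from 17 marker lists fixed before the data were examined, which gave 12 named classes and 3 unnamed clusters. The markers Ccl21a, Ighm and Trbc2 were not found in the files under those symbols. No cluster of the mesenchymal class had a marker of another class among its 10 leading genes over all cells. Mesenchymal cells, bone lineage included, were reclustered with 20 components at resolution 0.6 into 10 clusters. The clusters numbered 7 and 9, whose median UMI count was under 0.333 of the library's and whose leading genes held no mesenchymal marker, were left out of the class after the data were seen, which took 37 cells (1.35% of the library) from the Lmx1b library and 118 cells (5.11%) from the Pdgfra library. Leading genes of the remaining 8 clusters were ranked against other mesenchymal cells only, so that single markers of other classes (Mcpt4 in cluster 0, Mmp9 in cluster 4) appeared among them. Krt2, on no marker list but a leading gene of the epithelial cluster over all cells, was among those of cluster 1.

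With 1 library per mouse line there was no replicate, so no test, p-value or count of changed genes was made from cells. A cell was tdTomato-positive with at least 1 tdTomato UMI, as fixed before the data were examined. After the distribution of tdTomato per cell had been seen, a cell was also called labelled at 1600 CPM (parts of tdTomato among all UMIs of the cell, on the usual CPM scale) or more, and every comparison of labelled cells was added at that point. Shares were given with exact (Clopper-Pearson) 95% binomial intervals. UMIs were summed over the cells on each side of a comparison and expressed as CPM. Folds of those sums carry exact 95% intervals of the ratio of 2 Poisson counts, in brackets after the fold. Log2 differences used a pseudocount of 1 CPM. All intervals cover counting error only, and neither the spread between cells nor that between animals.

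The 18 gene lists were fixed before the data were examined: nail mesenchyme, digit tip blastema, limb patterning transcription factors, osteogenic, dermal and adventitial fibroblast, tendon and joint, extracellular matrix, matrix remodelling, cell cycle, Wnt, BMP, hedgehog, FGF and PDGF, and TGF-beta signalling, hypoxia and glycolysis, inflammation, dissociation stress, and sex chromosome. Some lists share members, Rspo3, Rspo4 and Wif1 being on both the nail mesenchyme and the Wnt list, so results of these lists are not separate. The nail mesenchyme list also holds Lmx1b itself. Cluster 5 below was picked out by that list, so its Lmx1b and nail values partly follow from the choice. Members with a mean of at least 5 CPM on both sides together counted as measured. Members at least 1.5-fold apart with an interval excluding 1 were counted as higher or lower. Each list's median log2 difference was given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, and with an interval from 200 Poisson resamples. All 18 lists are given for the comparison of all mesenchymal cells. Elsewhere the text gives the nail mesenchyme list, the lists whose median reached 1.5-fold, and a list that went opposite ways in the libraries, a choice made after the values were seen.

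Genes were named by a rule fixed before the data were examined: up to 10 with the largest log2 differences in each direction among those with at least 100 CPM and at least 30 UMIs on the higher side, at least 2-fold apart, with the nearer bound of the interval beyond 1.5-fold, leaving out tdTomato, mitochondrial and ribosomal protein genes and unnamed gene models. Lmx1b, Pdgfra and up to 4 members of each list were given besides. For tdTomato-positive against negative cells of the Pdgfra library only the top 4 in each direction are named, since 25 cells made up the negative side, and none for cluster 5, where 13 cells were unlabelled. Both were decided after seeing the values. The naming step was tested on simulated sums over 28001 genes with 200 changed. These sums were drawn with counting error only, so they cannot show how often spread between cells would yield a name. Genes changed 2-fold lay at the rule's own limit. The naming step named 100% of the genes changed 3-fold or more and 40% of those changed 2-fold for tdTomato-positive against negative cells of the Lmx1b library, and 52% and 8% of those changed 3-fold and 2-fold in the Pdgfra library, with 1 unchanged gene named. For labelled against unlabelled cells of the Lmx1b library it named 100% of the genes changed 3-fold and 50% of those changed 2-fold.

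To compare shares across depths, every cell was thinned to 5000 UMIs, which left out 560 cells of the Lmx1b library and 948 of the Pdgfra library as too shallow, 74 and 73 of them mesenchymal. Alternatives covered the filters (200 genes with 25% mitochondrial, 1000 genes with 5%), doublets, clustering (Leiden resolution 0.5 and 2.0, each library alone, mesenchymal resolution 0.3 and 1.0), at least 2 tdTomato UMIs, a pseudocount of 5 CPM, list members at 20 CPM or with no minimum, totals scaled by trimmed means of M values (TMM), the mean of each cell's CPM, thinning, matching on total UMIs, leaving out cells with 2 or more UMIs of 6 cycling genes, and weighting both sides to the same mix of those mesenchymal clusters with at least 10 cells on each side. Added after seeing the data were thresholds of 800 and 3200 CPM, leaving out Xist-positive cells, and keeping the low-UMI clusters. TMM shifted all genes by more than 0.1 on the log2 scale in labelled against unlabelled cells of the Lmx1b library (0.14) and of the Pdgfra library (0.16), and in tdTomato-positive against negative cells of the Pdgfra library (-0.31). Software was Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.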

Results

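The data were single-cell transcriptomes of regenerating digit tips of adult mice, taken 14 days after amputation from 2 lines of lineage-tracing mice, with 1 library per line and no replicate. Pdgfra encodes a platelet-derived growth factor receptor found on most fibroblast-like mesenchymal cells, and Lmx1b a LIM homeodomain transcription factor of the dorsal limb. Tamoxifen before amputation switched on tdTomato, a red fluorescent protein, in cells that used the driver gene, so that tdTomato marks those cells and their descendants in the regenerate. The study asked what mesenchyme associated with the nail gives to the dorsal side of the regenerating tip. The Lmx1b library kept 2744 cells and the Pdgfra library 2309 cells, at median depths of 17084 and 9774 UMIs.

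Mesenchymal cells were the largest class of both libraries and vascular cells came next. Mesenchymal cells made up 37.0% of the Lmx1b library (1014 cells, 95% interval 35.1 to 38.8%) and 27.0% of the Pdgfra library (623 cells, 25.2 to 28.8%), at nearly equal median depths of 26326 and 26275 UMIs. Endothelial cells made up 22.1% and 14.0%, pericytes and smooth muscle 11.4% and 9.83%, and macrophages and monocytes 4.01% and 5.02%. Epithelial cells numbered 94 in the Lmx1b library and 3 in the Pdgfra library, Schwann cells 36 and 95, erythroid cells 84 and 194, cartilage cells 132 and 113 (44 of the latter in a low-UMI cluster with another profile), osteoclasts 32 and 56, dendritic cells 25 and 24, T and NK cells 23 and 31, and neutrophils 21 and 4. Another 254 and 499 cells lay in the 3 unnamed clusters and the mesenchymal clusters left out. Class shares moved with the cell filter, and clustering the Pdgfra library alone gave 13.2% mesenchymal cells.

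Most mesenchymal cells of the Pdgfra library carried strong tdTomato, whereas in the Lmx1b library few did. At 1600 CPM or more, a threshold set after the values had been seen, 84.8% (81.7 to 87.5%) of mesenchymal cells were labelled in the Pdgfra library and 6.80% (5.33 to 8.53%, 69 cells) in the Lmx1b library. In the Lmx1b library 36 mesenchymal cells lay within a factor of 2 of the threshold, between 800 and 3200 CPM, and in the Pdgfra library 332 did, as did 25 and 21 endothelial cells. At 3200 CPM the labelled shares were 38.5% and 4.04%. Outside the mesenchyme, the Pdgfra library had labelled pericytes and smooth muscle cells (43.6%, 37.1 to 50.3%), endothelial cells (29.0%, 24.1 to 34.3%) and Schwann cells (28.4%), and fewer labelled macrophages (7.76%, and 24.1% at 800 CPM), cartilage cells (5.31% and 31.0%) and osteoclasts (5.36% and 19.6%), shares that rested on the threshold. The cartilage shares were lowered by the 44 low-UMI cells with another profile, at 46.7 CPM tdTomato against 942 CPM in the other cartilage cluster. In the Lmx1b library 0 of 606 endothelial cells were labelled, which allows a share of up to 0.607% (4.13% at 800 CPM, 2.69 to 6.03%), 0 of 110 macrophages (up to 3.30%), 0.319% of pericytes and smooth muscle cells, 0.758% of cartilage cells and 2.78% of Schwann cells.

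By the presence of a single tdTomato UMI, 79.1% (76.5 to 81.6%) of mesenchymal cells were positive in the Lmx1b library and 96.0% (94.1 to 97.4%) in the Pdgfra library. In the Lmx1b library that share lay above that of macrophages but not above that of endothelial cells. There 88.3% of endothelial cells carried a tdTomato UMI at less than 50% of the depth (median 12597 against 26326 UMIs), as did 53.6% of macrophages at a median of 26877 UMIs. In the Pdgfra library 84.6% of endothelial cells and 80.2% of macrophages (median 19903 UMIs) did. After thinning, 40.5% of mesenchymal, 70.7% of endothelial and 16.5% of macrophage cells were positive in the Lmx1b library, and 98.7%, 83.1% and 61.2% in the Pdgfra library. Since a single UMI was at least as frequent in endothelial cells of the Lmx1b library, where no Lmx1b UMI was found, labelled cells are reported beside the tdTomato-positive ones throughout.

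**Figure D1:**
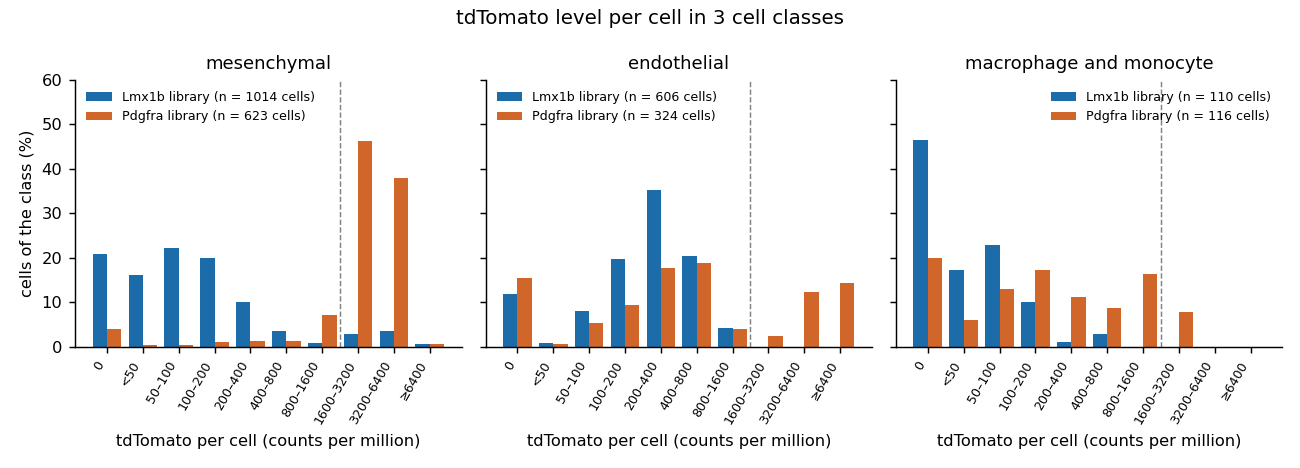
Percent of mesenchymal, endothelial, and macrophage and monocyte cells (vertical axis) by tdTomato level per cell in CPM (horizontal axis, in steps), with 1 bar per library and a dashed line at 1600 CPM. Most Pdgfra mesenchymal cells lie to the right of the line, against 6.80% of Lmx1b mesenchymal cells and no Lmx1b endothelial cell or macrophage.

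Within the mesenchyme of the Lmx1b library, labelled cells gathered in 2 of the 8 clusters. In cluster 5, led by Sfrp2, Cyp2f2, Epha5 and Apod and highest for the nail mesenchyme list, 28 of 41 cells were labelled (68.3%, 51.9 to 81.9%). In cluster 0, led by Mest and Gldn, 19.1% (13.0 to 26.6%) of 141 cells were. At 3200 CPM the shares of clusters 5 and 0 were 58.5% (24 of 41 cells) and 9.22% (13 of 141). These clusters held 40.6% and 39.1% of the labelled cells. Bone cells of cluster 3, led by Bglap, were 3.64% labelled (6 of 165), cells of cluster 1, led by Adamts18 and C1qtnf3, 0.952%, cells of cluster 2, led by Cilp2 and Thbs4, 1.29%, cycling cells of cluster 8 6.98% (3 of 43, 1.46 to 19.1%) and cells of cluster 6 0.935%. Cluster 4, led by Angpt2 and Fmo2, had 0 labelled of 152 cells, which allows up to 2.40%. In the Pdgfra library the labelled share was 96.6% (91.5 to 99.1%) in cluster 5 (114 of 118 cells), 92.5% in cluster 2, 75.0% in clusters 1 and 4, 93.3% in cluster 6 (A2m, Wisp2, Mmp13), 64.5% in the cycling cluster 8 and lowest in bone cluster 3 (11 of 44 cells, 13.2 to 40.3%, but 68.2% at 800 CPM, 29 of its cells lying within a factor of 2 of the threshold), and in cluster 0 it was 199 of 204 cells (94.4 to 99.2%). In cluster 1 of that library 90 of 112 cells lay within a factor of 2 of the threshold, and its share was 91.1% at 800 CPM. At 3200 CPM the shares were 72.0% in cluster 5, 66.7% in cluster 6, 48.0% in cluster 0 and 29.9% in cluster 2. They were 28.1% in cluster 4, 16.1% in cluster 8, 10.7% in cluster 1 and 2.27% in cluster 3. By a single UMI, 97.6% and 99.2% of cluster 5 were positive in the Lmx1b and Pdgfra libraries. Cluster 5 made up 4.04% of mesenchymal cells in the Lmx1b library and 18.9% in the Pdgfra library. The largest clusters also differed, being clusters 1 (20.7%) and 3 (16.3%) in the Lmx1b library and clusters 0, 5 and 1 (18.0%) in the Pdgfra library.

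**Figure D2:**
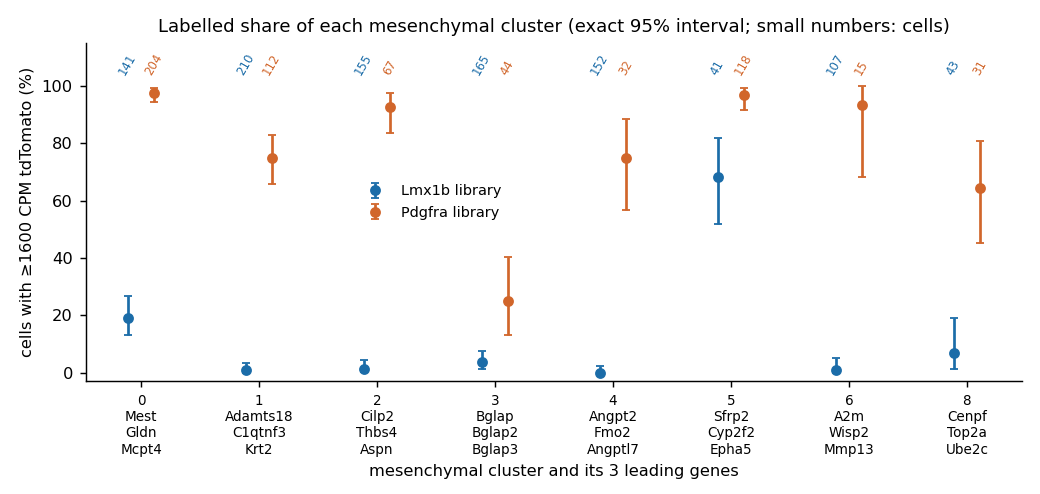
Percent of cells labelled at 1600 CPM or more (vertical axis) in each of 8 mesenchymal clusters (horizontal axis, with leading genes), by library, with exact 95% intervals and the number of cells above each point. In the Lmx1b library cluster 5 reached 68.3% and cluster 0 reached 19.1%, and the other clusters stayed under 10%.

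In the Lmx1b library the driver gene was detected more often in labelled than in unlabelled mesenchymal cells, though not in most labelled cells. A Lmx1b UMI was found in 30.4% (19.9 to 42.7%) of labelled and 2.65% of unlabelled mesenchymal cells at median depths of 24480 and 26399 UMIs, in 0 of 606 endothelial cells (up to 0.607%) and in 0 of 110 macrophages (up to 3.30%). Split by a single tdTomato UMI, 3.99% of positive and 6.60% of negative cells had one. Thinned shares were 8.06% (2.67 to 17.8%) of labelled and 0.683% (0.251 to 1.48%) of unlabelled cells. Inside cluster 5, however, Lmx1b stood at 32.1 CPM in labelled and 43.3 CPM in unlabelled cells (0.742-fold, 0.339 to 1.66). In the Pdgfra library, where Lmx1b is not the driver, 26.1% of labelled and 6.32% of unlabelled mesenchymal cells had a Lmx1b UMI, and in cluster 5 the share was 43.9% in the Lmx1b library and 72.0% in the Pdgfra library. A Pdgfra UMI was found in 82.6% of labelled and 83.6% of unlabelled mesenchymal cells of the Lmx1b library. Endothelial cells (4.79%) and macrophages (5.45%) there rarely had one. After thinning, the mesenchymal shares were 59.7% (46.4 to 71.9%) and 45.8% (42.5 to 49.1%). In summed counts Pdgfra stood at 230 CPM in labelled and 141 CPM in unlabelled cells (1.63-fold, 1.46 to 1.81). Inside clusters 0 (1.05-fold, 0.865 to 1.27) and 5 (1.01-fold, 0.804 to 1.27) it was alike. In the Pdgfra library the shares were 89.0% of labelled and 65.3% of unlabelled cells, at unlike median depths of 26876 and 17819 UMIs. After thinning they were 57.1% (52.5 to 61.5%) and 47.5% (34.6 to 60.7%), with overlapping intervals. In summed counts Pdgfra stood there at 175 against 121 CPM (1.45-fold, 1.29 to 1.63). Thinned shares with a Lmx1b UMI in that library were 9.82% (7.33 to 12.8%) of labelled cells and 0 of 61 unlabelled cells (up to 5.87%). Rspo4, an R-spondin needed for nail formation, was seen in 39.1% of labelled and 2.54% of unlabelled cells of the Lmx1b library. At least 2 UMIs of 6 cycling genes were found in 7.25% (2.39 to 16.1%) of labelled and 12.4% (10.3 to 14.7%) of unlabelled cells there. The shares were 12.0% of tdTomato-positive and 12.3% of tdTomato-negative cells, at unlike median depths of 28277 and 17097 UMIs. After thinning these were 5.65% (4.13 to 7.51%) and 8.70% (4.84 to 14.2%), with overlapping intervals.

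The first fixed comparison asked how tdTomato-positive mesenchymal cells of the Lmx1b library (802 cells) differed from negative ones (212 cells). Bone matrix genes were higher in positive cells and cell cycle genes lower. Of 12 measured osteogenic genes 7 were higher and 0 lower (median 1.42 on the log2 scale, 1.27 to 1.49, percentile 100), among them Spp1 (osteopontin, 4.34-fold, 4.23 to 4.44), Ibsp (bone sialoprotein, 2.90-fold, 2.86 to 2.94), Bglap (osteocalcin, 2.93-fold), Bglap2 (2.71-fold) and Ifitm5 (2.66-fold). Gal (galanin, 5.32-fold), Col2a1 (3.86-fold), Slpi (3.13-fold), Ramp1 (2.67-fold) and Sgms2 (2.63-fold) were higher too. Of 13 cell cycle genes 9 were lower in positive cells (median -0.67, percentile 0), with Top2a 2.14-fold and Cdk1 1.70-fold lower. Mmp9 (3.22-fold), Tagln (2.30-fold), Gldn (2.20-fold) and Mest (2.11-fold) were the other named genes lower in positive cells. The nail mesenchyme list had a median of -0.25 (-0.34 to -0.15, percentile 1.09), with Wif1 (1.71-fold) higher and none of its 6 measured members lower by 1.5-fold, and the dermal and adventitial fibroblast list a median of -0.33 with Pi16 and Pcolce2 higher and Gsn lower of 9 measured. Lmx1b itself stood at 1.89 CPM in positive and 3.69 CPM in negative cells, and Pdgfra at 147 and 140.2 CPM.

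These differences depended on how cells were weighted. By the mean of each cell's CPM the osteogenic median was 0.10 and the cell cycle median -0.26, and with both sides weighted to the same mix of clusters, cluster 5 left out for its 1 negative cell, the osteogenic median was 0.07, the cell cycle median -0.13, the nail median 0.066 and the dermal median 0.19. Positive cells had a median of 28277 UMIs and negative cells 17097, and matched on total UMIs the medians were 1.27 for osteogenic, -1.20 for cell cycle and 0.066 for nail genes. Gal (-0.24) and Col2a1 (-0.21) turned with the filter of 200 genes and 25% mitochondrial UMIs, Mmp9 (1.01) with that of 1000 genes and 5%, and Bglap (-0.053), Bglap2 (-0.047) and the dermal list (0.18) by the mean of each cell's CPM.

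Called at 1600 CPM instead, labelled mesenchymal cells of the Lmx1b library (69 cells) differed strongly from unlabelled ones (945 cells). They expressed genes of the nail mesenchyme and of Wnt signalling far more and genes of bone less, and cell cycle genes were lower in the summed counts. Of 9 nail mesenchyme genes 7 were higher and only Mme was lower (median 1.71, 1.64 to 1.78, percentile 100), with Rspo4 18.9-fold, Corin 17.3-fold, Lmx1b 13.9-fold (8.10 to 23.7) and Msx1 3.28-fold higher. Lmx1b stood at 17.0 against 1.22 CPM. Of 15 Wnt signalling genes 11 were higher and Dkk1 was lower (median 1.58, percentile 100), among them Sfrp2, a secreted Wnt modulator, at 5080.4 against 202.2 CPM (25.1-fold), Rspo1 (9.58-fold) and Dkk2 (5.33-fold). The other named genes higher in labelled cells were Cyp2f2 (19.3-fold), Igfbp2 (17.4-fold), the ephrin receptor gene Epha5 (16.9-fold), Cck (12.5-fold), Cybrd1 (11.1-fold), Steap1 (9.81-fold), the activin antagonist gene Fst (9.46-fold), Xist (9.45-fold) and Apod (9.27-fold).

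Bone genes were lower in the labelled cells, 10 of 12 measured (median -1.75, -1.92 to -1.50, percentile 0), with Bglap 33.1-fold, Bglap2 21.7-fold and Phex 19.9-fold lower. Of 12 cell cycle genes 8 were lower (median -1.18, percentile 0), with Ube2c 12.1-fold and Top2a 5.88-fold lower. Few labelled cells were cycling, however, 5 of 69 having at least 2 UMIs of 6 cycling genes. Their share of 7.25% (2.39 to 16.1%) overlapped in interval with the 12.4% (10.3 to 14.7%) of unlabelled cells. Of 7 inflammation genes 3 were lower (median -0.79), led by Saa3, an acute phase gene with 3 UMIs in labelled cells (130-fold lower, 44.3 to 628), Cxcl1 (7.02-fold) and Ccl2 (5.46-fold). The matrix remodelling list had a median of -0.37, with 6 of 14 members lower, among them the collagenase gene Mmp13 (11.6-fold). Sfrp4 (14.4-fold), Prg4 (lubricin, 9.57-fold), Rgs5 (7.65-fold), Gal (6.94-fold), C1qtnf3 (5.76-fold) and Enpp1 (5.43-fold) were also lower. Xist-positive cells made up 13 of the 69 labelled cells and 28 of all 1014 mesenchymal cells of this library, and without them the nail median was 1.64. Weighted to the same mix of clusters, which only clusters 0 and 5 could enter with 10 labelled cells, the nail median was 0.14, the Wnt median 0.16, the osteogenic median -0.43 and the cell cycle median -0.11. The inflammation median (0.27), Cyp2f2 (-0.28) and Gal (1.43) turned to the other direction there.

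Inside cluster 0 of the Lmx1b library, 27 labelled cells could be set against 114 unlabelled cells at like median depths of 28541 and 28408.5 UMIs. Nail mesenchyme genes were higher in the labelled cells of this cluster too, 6 of 9 (median 0.71, 0.54 to 0.84, percentile 100), with Corin 3.30-fold, Lmx1b 2.70-fold (1.03 to 6.70), Rspo3 2.20-fold and Msx1 1.67-fold higher and Mme 3.69-fold lower. Epha5 (4.87-fold), Igfbp2 (3.59-fold), the chemokine gene Cxcl14 (3.51-fold), Nell2 (3.39-fold), Mgst1 (2.54-fold), Id1 (2.07-fold), Steap2 (2.07-fold) and Ntrk2 (2.02-fold) were higher, and Mmp13 (30.4-fold), Prg4 (17.1-fold), Rgs5 (6.77-fold), H19 (3.02-fold), Comp (2.67-fold), Mpp6 (2.59-fold), Sertad4 (2.504-fold) and Mef2c (2.17-fold) lower. In cluster 5, where 13 cells were unlabelled, the nail median was -0.18 (-0.26 to 0.11). There dissociation stress genes were lower in labelled cells, 5 of 12 (median -0.74, -0.89 to -0.36), and osteogenic genes had a median of 0.69 (0.28 to 1.01) with Ibsp, Spp1 and Alpl higher of 9. The cell cycle median there was 0.98 (-0.31 to 3.10) over 3 measured genes.

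The same contrast in the Pdgfra library set 598 tdTomato-positive cells against 25 negative cells, which had a median of 2566 UMIs against 27066. The negative cells, summed, carried female and imprinted transcripts (Xist at 436 and H19 at 1111 CPM), as low-UMI barcodes set aside from that library did, and many genes of the positive cells had no UMI in them. Of 4 measured sex chromosome genes only Xist was 1.5-fold apart, so the negative cells held Y-linked transcripts too. Xist was 772-fold lower in positive cells (378 to 1702), H19 24.9-fold, Mest 5.17-fold and Rbp4 4.56-fold lower. Gpm6b (at least 4.22-fold), Svep1 (at least 4.09-fold), Ltbp2 (at least 3.41-fold) and Sfrp1 (at least 3.27-fold) were higher against a floor of 3 UMIs over the negative group, the exact lower limits being 3.43, 3.32, 2.77 and 2.66. Of 12 cell cycle genes 5 were lower in positive cells (median -1.58, percentile 0), of 12 dissociation stress genes 7 were (median -0.78), of 15 matrix remodelling genes 3 were (median -1.06, -1.18 to 0.03) and of 7 inflammation genes 2 were (median -0.86, -1.60 to 1.58). Of 8 dermal and adventitial fibroblast genes 4 were higher (median 1.34, 0.72 to 2.65), Ly6a 7.32-fold and Mfap5 3.27-fold. The nail mesenchyme median was 0.26 (-0.03 to 1.49), a difference from 0 not detectable at this depth, and Lmx1b stood at 14.7 and 14.1 CPM (1 UMI in negative cells). Stricter filters left so few negative cells that the cell cycle median was 3.79, and H19, Svep1 and Ltbp2 changed direction. Ltbp2 also did so with the low-UMI clusters kept (-0.077), and the dissociation stress median after thinning (0.50), when 543 of 550 cells were positive.

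Labelled cells of the Pdgfra library (528) against unlabelled cells (95, median depth 17819 against 26876 UMIs) showed the same direction as in the Lmx1b library for nail, Wnt and bone genes. The unlabelled sides were unlike, however, at 983 CPM tdTomato here against 110 CPM in the Lmx1b library. Of the 95 unlabelled cells, 44 lay between 800 and 1600 CPM and 25 had no tdTomato UMI. By cluster, 33 were bone cells of cluster 3 and 28 were cells of cluster 1, so label and cluster mix were not separated. Of 9 nail mesenchyme genes 7 were higher (median 1.86, 1.63 to 2.11), with Corin 13.9-fold, Rspo4 5.81-fold and Lmx1b 4.31-fold (2.31 to 9.08). Of 15 Wnt signalling genes 10 were higher (median 0.96), and of 12 osteogenic genes 11 were lower (median -1.97), among them Bglap (9.63-fold), Phex (8.89-fold) and Spp1 (7.54-fold). Of 12 cell cycle genes 7 were lower (median -0.68), but the median was 1.57 with the stricter filter and 0.050 after thinning. Higher medians were also found for the dermal and adventitial fibroblast list (1.45, 6 of 8 higher), the digit tip blastema list (0.93, 8 of 10, with Mdk 3.47-fold and Mest 2.44-fold), limb patterning transcription factors (0.91, 8 of 15, with Hoxd11 3.58-fold), tendon and joint (0.72, 4 of 8), matrix remodelling (0.72, 8 of 14) and FGF and PDGF signalling (0.60, 7 of 14). Dissociation stress genes were higher in the labelled cells, 11 of 12 (median 1.10), beside all of these lists.

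By gene, Epha5 (47.0-fold, 22.8 to 117), Sfrp2 (16.1-fold), Igfbp2 (5.42-fold), Cxcl14 (5.09-fold), Gldn (5.01-fold), Mfap5 (4.62-fold), Dkk2 (4.52-fold), Mfap4 (4.33-fold), Col23a1 (4.32-fold) and Svep1 (4.31-fold) were higher in labelled cells of the Pdgfra library, and Dkk1 (9.33-fold), Col11a2 (8.30-fold), Gal (7.68-fold), Slpi (7.61-fold), Col9a3 (7.26-fold), Slc13a5 (6.88-fold) and Col9a1 (6.47-fold) lower. Weighted to the same mix of clusters 1, 3 and 8, the others having fewer than 10 unlabelled cells, the nail median was 0.26, the dissociation stress median -0.059 and Igfbp2 -1.56. Igfbp2 also turned with the stricter filter (-0.40), Gal with 200 genes and 25% mitochondrial UMIs (0.52) and Col9a1 at 800 CPM (0.39). At 3200 CPM the nail median was 0.98 and that of the blastema list -0.078.

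Between the lines, all mesenchymal cells of the Lmx1b library (1014 cells) had higher list medians for inflammation and bone genes than those of the Pdgfra library (623 cells), and lower ones for Wnt and stress genes. Saa3 was 31.2-fold (26.4 to 37.2), Bglap 8.46-fold, Bglap2 7.36-fold, Sfrp4 5.46-fold, Wisp2 3.798-fold, Mmp13 2.64-fold, Mgp 2.35-fold, Slpi 2.20-fold and Kazald1 2.17-fold higher in the Lmx1b library. Cyp2f2 was 6.47-fold, Epha5 3.45-fold, Apod 3.29-fold, Igfbp2 3.21-fold, AY036118 3.16-fold, Zfp36 3.14-fold, Tnmd 2.53-fold, Meg3 2.29-fold, Apoe 2.23-fold and Socs3 2.23-fold lower. Lmx1b stood at 2.13 against 14.7 CPM and Pdgfra at 146 against 168 CPM.

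By list, inflammation had a median of 0.83 with 5 of 7 members higher (Cxcl5 5.63-fold, Cxcl12 2.15-fold) and Ptgs2 lower, osteogenic 0.63 with 7 of 12 higher, hypoxia and glycolysis 0.42 with 3 of 11 higher (Adm 2.01-fold), dermal and adventitial fibroblast 0.32 with 2 of 9 higher, cell cycle 0.28 with 1 of 13 higher, matrix remodelling 0.23 with 4 of 14 higher, extracellular matrix 0.22 with 1 of 15 higher and 2 lower, and hedgehog signalling 0.19 with 1 of 6 higher. Dissociation stress had a median of -0.52 with 5 of 12 members lower (among them Zfp36 and Fos), Wnt signalling -0.48 with 6 of 15 lower (Rspo1 2.85-fold) and Notum higher, tendon and joint -0.30 with 2 of 7 lower, nail mesenchyme -0.22 with 4 of 9 lower (Rspo4 3.96-fold), BMP signalling -0.16 with 2 of 12 lower and the sex chromosome list -0.14 with Xist higher of 5. Digit tip blastema (-0.09, 1 of 10 higher and 2 lower), limb patterning transcription factors (-0.02, 1 of 15 higher and 3 lower), FGF and PDGF signalling (0.02, 2 of 15 higher and 1 lower) and TGF-beta signalling (-0.03, 1 of 11 higher) had medians within 0.1 of 0. The line and the library could not be separated, and the clusters that held most of the class differed between the libraries, as given above. Weighted to the same mix of clusters the nail median was 0.070 and the osteogenic median 0.14, and under the stricter filter of 1000 genes and 5% mitochondrial UMIs the inflammation median was -0.024, the dermal median -0.44, the cell cycle median -0.16, the hedgehog median -0.19 and Mgp -0.016.

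Restricted to tdTomato-positive cells (802 against 598), the lines differed much as all mesenchymal cells did. These were 79.1% and 96.0% of the same mesenchymal cells, so the likeness is no separate evidence. Saa3 was 34.7-fold, Bglap 9.26-fold, Bglap2 8.03-fold, Sfrp4 5.83-fold, Wisp2 3.98-fold, Mmp13 2.77-fold, Slpi 2.43-fold, Gal 2.37-fold and Kazald1 2.32-fold higher in the Lmx1b library. Cyp2f2 (5.64-fold), Igfbp2 (3.38-fold), Epha5 (3.32-fold), Apod (3.23-fold), AY036118 (3.23-fold), Zfp36 (3.14-fold), Tnmd (2.71-fold), Meg3 (2.40-fold), Apoe (2.35-fold) and Socs3 (2.24-fold) were lower. Inflammation genes had a median of 0.88 with 5 of 7 higher and Ptgs2 lower, osteogenic genes 0.69 with 8 of 12 higher, and nail mesenchyme genes -0.29 with 4 of 9 lower, Lmx1b being at 1.89 against 14.7 CPM. With the stricter filter the inflammation median was -0.045, with 200 genes and 25% mitochondrial UMIs Gal was -1.68, and with the same mix of clusters the nail median was 0.047.

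Restricted to labelled cells (69 against 528), the direction for nail genes turned. Of 9 nail mesenchyme genes 6 were higher in the Lmx1b library (median 1.03, 0.78 to 1.10), with Corin 2.82-fold and Msx1 2.29-fold, while Lmx1b was alike at 17.0 and 16.4 CPM. Of 15 Wnt signalling genes 10 were higher (median 0.87), Sfrp2 6.58-fold and Notum 6.11-fold, and of 12 cell cycle genes 6 were lower (median -0.62), with only 5 of the 69 cells cycling as given above. Xist (at least 735-fold against a floor of 3 UMIs over the Pdgfra cells, exact lower limit 592), Ifi27l2a (4.69-fold), the BDNF receptor gene Ntrk2 (4.09-fold), C4b (3.87-fold), Cybrd1 (3.59-fold), the retinoic acid hydroxylase gene Cyp26b1 (3.28-fold), Fst (2.89-fold), Dpep1 (2.79-fold) and Steap1 (2.78-fold) were higher, and Rgs5 (12.2-fold), Prg4 (7.28-fold), C1qtnf3 (4.71-fold), Mmp13 (4.55-fold), AY036118 (3.10-fold), Zfp36 (2.84-fold), Socs3 (2.71-fold), Erdr1 (2.46-fold), Mt1 (2.26-fold) and Inhba (2.20-fold) lower. Without Xist-positive cells the nail median was 0.23, with the same mix of clusters 0 and 5 it was 0.17, and at 800 CPM the cell cycle median was 0.015.

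The single-UMI and the 1600-CPM calls often gave opposite directions. Among the 18 lists, both intervals excluded 0 for 8 lists in the Lmx1b library, and 5 of these had opposite signs. In the Pdgfra library it was 1 of 5 lists, and between the libraries 10 of 14.

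On mm10, in the GENCODE vM21 annotation, the protein-coding genes discussed most lie on chromosome 2 (Lmx1b, 33560965 to 33640511, and Rspo4, 151842927 to 151874668), chromosome 5 (Pdgfra, 75152292 to 75198215, and Msx1, 37820485 to 37824583), chromosome 3 (Sfrp2, 83766321 to 83774316, and Bglap, 88383501 to 88384464) and chromosome 1 (Igfbp2, 72824503 to 72852474). Their identifiers are ENSMUSG00000038765 for Lmx1b, ENSMUSG00000029231 for Pdgfra, ENSMUSG00000027996 for Sfrp2, ENSMUSG00000032852 for Rspo4 and ENSMUSG00000074483 for Bglap.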

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

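Of the tests in this part, only that of barcode sharing between the libraries was written before its result was seen, and the others were chosen after it.

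In the Lmx1b library 88.3% of endothelial cells carried a tdTomato UMI, a class in which Lmx1b was not detected. Free RNA is argued against as the whole source, since the ratio of tdTomato to Col1a1 UMIs was 7.28 times (6.10 to 8.68) higher in endothelial cells than in macrophages, where 1 source would keep it equal. Recombination in some of these cells stays open, since none of the 606 reached 1600 CPM (upper limit 0.607%) but that threshold was set after the levels had been seen, and 25 cells (4.13%, 2.69 to 6.03%) reached 800 CPM. A candidate explanation is low reporter transcription without recombination, since endothelial cells below the threshold had nearly equal median levels in both libraries (240.5 and 235.6 CPM, ratio 1.02) while tdTomato over all barcodes was 234 and 1990.3 CPM. Macrophages below it did not match (28.3 and 131 CPM). Mesenchymal cells (69.3 and 705 CPM), cartilage cells (54.9 and 302), pericytes and smooth muscle (49.3 and 122) and Schwann cells (121 and 213) did not either. These medians were all taken after cutting at the threshold. Low reporter transcription thus stays a hypothesis found and tested on the same data, and a biological explanation was not tested.

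Labelled cells of the Lmx1b library concentrated in cluster 5, the cluster highest for nail mesenchyme genes (68.3% labelled). Free RNA is argued against, since 0 of 110 macrophages reached the same level (upper limit 3.30%). The library held both Xist-positive and Y-positive cells. Of the 41 cells of cluster 5, 16 were Xist-positive (39.0%), against 12 of 973 in the other mesenchymal clusters (1.23%). In cluster 5, 12 of these 16 were labelled, so animals of different sex might have produced the pattern. Among Y-positive cells alone, however, 8 of 15 cells of cluster 5 were labelled (53.3%, 26.6 to 78.7%). In the other mesenchymal clusters 30 of 671 were (4.47%, 3.04 to 6.32%). On these few cells of cluster 5, this argues against a difference between male and female animals as the whole cause. It leaves open animals of the same sex that differed in recombination. A lineage relation between cells that used Lmx1b before amputation and this cluster remains a hypothesis, as does use of Lmx1b by these cells while tamoxifen persisted, which was not tested.

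Some low-UMI barcodes held profiles that differed from the rest of their library, in data the comparisons do not use: 64 barcodes in the Lmx1b library with Gfap (1037 CPM), Aqp4 (511 CPM) and Mt3 (6188 CPM), genes of astrocytes, and 129 in the Pdgfra library with Xist (488 CPM), the imprinted genes H19 (519 CPM) and Igf2 (895 CPM) and the gene model Gm10260 (354 CPM). The 129 barcodes also held 42 UMIs of Y-linked genes beside 171 of Xist. Free RNA of the same library was not decided. Among barcodes of 500 to 4000 UMIs, 1.56% and 11.2% of those with another profile carried a tdTomato UMI, against 27.9% and 67.9% of the others. The others include labelled cells, so they do not measure free RNA. Their median depth was higher in the Lmx1b library (1561 against 935 UMIs) but lower in the Pdgfra library (1605.5 against 2086 UMIs). Depth thus could not account for the lower share in the Pdgfra library. Barcodes shared between these libraries are argued against as the source of most barcodes with another profile, since 0% (up to 5.60%) and 0.775% (0.02 to 4.24%) occurred in the other library, against 0.112% and 0.138% of the other kept barcodes. The 25 tdTomato-negative mesenchymal cells of the Pdgfra library, which a comparison does use, also held Xist (436 CPM) and H19 (1111 CPM) when summed, at a median of 2566 UMIs, though only 8 of all 623 mesenchymal cells there were called Xist-positive. RNA or cells from a different sample could be a source, which no file here could test.

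The dermal and adventitial fibroblast list went opposite ways in tdTomato-positive against negative cells, at -0.33 in the Lmx1b library and 1.34 in the Pdgfra library, a difference of -1.67 that was not tested and rests on 25 negative cells in the latter. The value of the Lmx1b library was above 0 after thinning (0.15), by the mean of each cell's CPM (0.18) and with the same mix of clusters (0.19), and the directions were alike under that mean. Thinning left 543 of 550 cells of the Pdgfra library positive, too few negative ones to compare, and the same mix gave no value there. The matrix remodelling list went opposite ways in labelled against unlabelled cells, at -0.37 and 0.72, a difference of -1.09 that was not tested either, the latter value being 0.035 at 800 CPM. Mesenchymal cells of the Pdgfra library held 29 UMIs of a CreERT2 feature (1.48 CPM), and those of the Lmx1b library 3 UMIs (0.105 CPM). In the Pdgfra library, 4.49% of mesenchymal cells had such a UMI, against 0.309% of endothelial cells (1 UMI) and 0 of 116 macrophages. Their median depths were 26275, 10526 and 19903 UMIs. No cell was called from this feature.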

How the results depend on the processing

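Settings from the threshold of 800 or 3200 CPM, the labelled comparisons, leaving out Xist-positive cells and keeping low-UMI clusters were chosen after the data were seen. Across the planned settings 284 of 302 values of 24 list medians and 686 of 697 values of 64 gene results kept their sign. Across the added ones 286 of 295 values of 45 list medians and 966 of 974 values of 145 gene results did. A kept sign was not a kept size. With shares included, 36 planned values of the headline results were counted as moved, 7 as reversed and 56 as the same. For the other results these numbers were 650, 22 and 664. The cause of each change below was not tested, unless the setting itself names it. No paired analysis was possible because each line has 1 library. Weighting to the same mix of clusters gave no value for tdTomato-positive against negative cells of the Pdgfra library, where no cluster had 10 cells on both sides. Below, "positive" stands for tdTomato-positive against negative cells, "labelled" for labelled against unlabelled cells, and list values are median log2 differences.

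With 200 genes and 25% mitochondrial, mesenchymal shares were 23.9% (Lmx1b library) and 18.99% (Pdgfra library), tdTomato-positive shares 68.1% and 87.2% of mesenchymal cells and 86.9% and 90.6% of the cluster highest for the nail list. In positive cells of the Lmx1b library the nail list was 0.13, Col2a1 -0.21 and Gal -0.24. Between the lines the nail list was -0.20 in positive and -0.16 in all mesenchymal cells, and Gal -1.68 in positive cells. Labelled shares were 9.13% and 74.3% and 83.6% in the Pdgfra cluster, with the nail list at 1.64 and 0.92 in labelled cells of the 2 libraries, and the blastema list at -0.14 and Gal at 0.52 in the Pdgfra library.

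With 1000 genes and 5% mitochondrial, mesenchymal shares were 47.9% and 23.3%, the tdTomato-positive share was 87.1% in the Lmx1b library, and all Pdgfra cells of the cluster were positive (100%). Mmp9 was 1.01 in positive cells of the Lmx1b library. In the Pdgfra library, where the setting left few negative cells, the nail list was 5.11, the cell cycle list 3.79, H19 5.19, Ltbp2 -0.50 and Svep1 -1.10. Between the lines the nail list was -0.69 and the inflammation list -0.045 in positive cells. In all mesenchymal cells the nail list was -0.73, the dermal list -0.44, cell cycle -0.16, hedgehog -0.19, inflammation -0.024 and Mgp -0.016. Labelled shares in the Pdgfra library were 81.1% and, in the cluster, 100%. The nail list was 2.27 in labelled cells of the Lmx1b library, and cell cycle was 1.57 and Igfbp2 -0.40 in those of the Pdgfra library.

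At Leiden resolution 2.0, mesenchymal shares were 32.8% and 24.0%, with 93.0% of Pdgfra mesenchymal cells and 90.7% of its cluster positive and 87.6% of the cluster labelled. The nail list was 1.504 in labelled cells of the Lmx1b library and 0.69 between labelled cells of the lines. Each library clustered alone gave 13.2% mesenchymal cells in the Pdgfra library. At mesenchymal resolution 0.3, 91.9% of the Pdgfra cluster was positive. With no doublets removed, 94.0% of Pdgfra mesenchymal cells and 91.2% of its cluster were positive, 88.2% of the cluster was labelled, and the nail list was 1.58 in labelled cells. With low-UMI clusters kept, the Pdgfra mesenchymal share was 32.1%, with 85.6% positive and 74.0% labelled. There the nail list was -0.043 in positive and 1.57 in labelled cells, and Ltbp2 was -0.077.

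Thinned to 5000 UMIs, the positive shares were 40.5% and 98.7% of mesenchymal cells and 84.6% and 100% of the cluster, and 1.57% of Lmx1b-library cells called positive after thinning had a Lmx1b UMI. The nail list was 0.24 and the dermal list 0.15 in positive cells of the Lmx1b library, and nail was 1.65 and stress 0.50 in those of the Pdgfra library, where cell cycle was 0.050 in labelled cells. Matched on total UMIs, the nail list was 0.066 and 1.49 in positive cells. With at least 2 tdTomato UMIs, 57.6% of mesenchymal cells of the Lmx1b library were positive and the nail list between positive cells of the lines was -0.44.

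By the mean of each cell's CPM, positive cells of the Lmx1b library had the nail list at 0.035, dermal at 0.18, Bglap at -0.053 and Bglap2 at -0.047, and the nail list between all mesenchymal cells was -0.33. With the same mix of clusters, cluster 5 left out, they had nail at 0.066, dermal at 0.19 and Bglap2 at -0.0043. Between the lines nail was then 0.047 in positive and 0.070 in all cells, and BMP 0.013. In labelled cells of the Lmx1b library (clusters 0 and 5 only) nail was 0.14, inflammation 0.27, Cyp2f2 -0.28 and Gal 1.43, in those of the Pdgfra library (clusters 1, 3 and 8 only) nail was 0.26, stress -0.059 and Igfbp2 -1.56, and between labelled cells of the lines (clusters 0 and 5 only) nail was 0.17. List members at 20 CPM gave nail medians of -0.17 and -0.13 between the lines in positive and all cells, and leaving out cycling cells gave -0.30 in all cells.

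Called at 1600 CPM in place of 1 UMI, the nail list was 1.71 and 1.86 within the libraries and 1.03 between them. Without Xist-positive cells it was -0.35 in positive and 1.64 in labelled cells of the Lmx1b library, where Xist was -0.031 by construction, and 0.23 between labelled cells of the lines. At 800 CPM, 91.8% of Pdgfra mesenchymal cells and 99.2% of its cluster were labelled. The nail list was 1.58 and 1.09 within the libraries and 0.76 between them, Col9a1 was 0.39 in the Pdgfra library, and cell cycle 0.015 between the lines. At 3200 CPM the labelled shares were 4.04% and 38.5%, and 72.0% in the Pdgfra cluster. The nail list was then 2.16 and 0.98 within the libraries, 0.70 between them and 1.08 within cluster 0, and the blastema list was -0.078 in the Pdgfra library. TMM-scaled totals gave 1.57 for the nail list in labelled cells of the Lmx1b library.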

Other observations

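Vascular and nerve cells shared in the tdTomato label of the Pdgfra library. At 1600 CPM or more, 99 of 227 pericytes and smooth muscle cells, 94 of 324 endothelial cells and 27 of 95 Schwann cells were labelled, and 26.5% of endothelial cells and 34.8% of pericytes and smooth muscle cells still were at 3200 CPM, against 0 of 116 macrophages (up to 3.13%). Erythroid barcodes, at a median of 1378 UMIs, were 60.3% labelled and 30.9% at 3200 CPM. Few UMIs suffice for a single barcode to reach these levels. Summed, however, the erythroid barcodes held 2327 CPM tdTomato (2183 to 2478, 967 UMIs), against 1990 CPM over all barcodes of the library. The source of this tdTomato was not tested.

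For the higher nail mesenchyme genes in labelled cells of cluster 0 of the Lmx1b library, it was asked whether Xist-positive cells accounted for them, in a test written before its result was seen. No cell of that cluster was Xist-positive, so leaving them out removed 0 cells and could not change the median of 0.71 (27 against 114 cells). The removal was thus no test, but it shows that Xist-positive cells stood on neither side of this contrast. Cells without a call are not covered, 300 of the 1014 mesenchymal cells of the library having neither an Xist nor a Y call.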
